A study of Mus musculus with 10 samples.

How the data were processed

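RNA sequencing was carried out on stomach, duodenum, jejunum, ileum and colon of male C57BL/6J mice after vertical sleeve gastrectomy (VSG) or sham surgery, per the labels. The labels give 1 library for each of the 10 combinations of tissue and surgery. They do not say how many animals stand behind a library, whether the libraries came from separate animals, or how long after surgery the tissues were taken. The p-values below therefore measure only the spread between these libraries, which may be technical, and no difference within a tissue has a replicate check. If libraries of the same surgery came from the same animals, a difference between animals cannot be told apart from surgery.

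Total RNA was extracted with TRIzol and made into TruSeq libraries, per the labels' protocols. The submitters' processing notes name GSNAP, Cufflinks and the mouse build mm10, with no versions and no roles. The annotation and the filters are not given in the sources used here. The authors deposited 1 table of RPKM values (reads per kilobase of gene, scaled to the depth of the library), with 23079 genes by Entrez identifier and 1 column per library. Symbols were found for 23008 of the identifiers (99.69%), and the other 71 were left unnamed. Coordinates are those of the RefSeq annotation of GRCm38, the assembly that mm10 stands for.

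In the deposited table, the 8 intestinal columns stood 1 row below the gene identifiers and the stomach columns between rows 27 and 18213, a block of 18187 rows. In the row of Selenof, for example, the sham stomach value was 111 RPKM and the sham jejunum value 1.17 RPKM, while the sham jejunum value in the first row of the block was 120 RPKM. In all 147 windows of 100 genes inside the block that held enough expressed genes, the mean of 7 intestinal libraries correlated best with the mean of the stomach libraries at an offset of 1 row, and in all 44 windows outside it at an offset of 0. The 8 columns were moved back by 1 row. The repair was checked on the values themselves. Where whole reads are divided by a gene's length and a library's depth, the values of 1 gene in all libraries must return whole reads at 1 length of at most 150000 bases. Of 1579 genes sampled from the block, 36 (2.28%) did so as deposited and 1576 (99.81%) did so after the move. Over the whole table, 18333 of 18348 rows with values in stomach and intestine did so, and the other 15 were left out. The repair assumes that no row is missing between neighbouring rows, which these values cannot rule out for genes of very low expression. Results with the rows as deposited are among the alternatives.

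Depth was estimated from the same steps. For genes with a value above 0 in at least 4 libraries, 18577 of 18580 returned whole reads in every library within a tolerance of 0.001 reads. The common scale came from genes with a single annotated transcript. The recovered reads on genes ranged from 36036619 (VSG jejunum) to 79260603 (sham stomach). They were used only for exact conditional binomial (Clopper-Pearson) 95% intervals of ratios between the VSG and sham library and for a floor of 3 reads where a library had 0. These intervals cover counting error only. The recovered reads were 0.857 times the depth that the authors' values imply in the library labelled sham duodenum and 1.16 times in the VSG duodenum library, and the product of the ratios of sham and VSG lay between 0.992 and 0.998 in every tissue. Values are therefore comparable within a tissue pair on the authors' scaling, and rescaling all libraries to 1 total was run as an alternative.

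Within each tissue, genes with a mean of at least 1 RPKM over the 2 libraries were kept, and the difference was log2((VSG RPKM + 1)/(sham RPKM + 1)). The pseudocount of 1 understates the change of genes of low expression. With 1 library per group there is no test, and a gene was called higher or lower at 2-fold or more on that scale. Changes shared over tissues were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with the tissue as a block, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, over genes with a mean of at least 1 RPKM. The same model was fitted to the 3 segments of small intestine. Tissue differences set each tissue against the mean of the other 4 with surgery as an additive term, at an adjusted p under 0.05 and at least 2-fold.

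For this work 53 gene lists were written before the data were examined, of which 4 hold regional identity genes and served only to look at the tissue labels and at shifts along the gut within a tissue. Within a tissue, the median log2 difference of each list with at least 5 genes was given its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, and lists beyond the 2.5 and 97.5 percentiles are described. This describes the libraries and is not a test. Over the 5 tissues, lists were tested with camera from limma at the preset correlation of 0.01 between genes, and again with an estimated correlation. The interaction of the stomach change with the change of the other pairs was fitted with limma on the differences.

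Genes are named by a rule written before the data were examined. Predicted and clone names and immunoglobulin or T cell receptor segments were left out. Within a tissue the rule takes the 10 largest and 10 smallest log2 differences among genes with at least 5 RPKM in the higher library. For tests over tissues it takes the 10 genes with the smallest p in each direction among those with the same sign in every tissue of the fit, and for tissue differences the 5 largest among called genes. From each list it takes up to 4 members with the largest difference, or the members at or over 2-fold. A few genes that this rule takes are not reported here. A set of 9 hormone genes and 4 bile acid genes was read in every tissue. Members of near-identical families (Defa, Try, Amy2a, Reg3, Mup, Gsdmc and Saa genes) are uncertain one by one, since the authors' counting could split their reads.

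The steps were tested on simulated data made from the real values, with normal noise drawn independently for each gene and 200 changed genes. Read depth was not simulated. In the limma simulations the changed genes had a mean of at least 5 RPKM, so recovery of genes of lower expression was not tested. With the spread of all 5 pairs, the fit over 5 tissues recovered 14% of genes changed by 2-fold and 53% of those changed by 4-fold. The fit to the small intestine recovered 0% at both sizes with that spread. With the spread of the jejunum, ileum and colon pairs alone, the fit over 5 tissues recovered 78% and 95%, the fit to the small intestine 59% and 86%, and the fit to jejunum, ileum and colon 58% and 91%. The tissue difference for colon recovered 2% and 28% with the spread of all 5 pairs and 89% and 97% with the smaller spread. The interaction for stomach recovered 0% and 54% with the smaller spread. With the smaller spread, the camera test called all 5 lists planted at 2-fold, all 5 at 4-fold and 0 of 40 unchanged lists. As the noise was independent between genes, this does not show how often camera calls unchanged lists whose genes vary together. The spread of all 5 pairs was not simulated for camera. The percentile rule in ileum picked out all 5 planted lists at each size and 2 of 40 unchanged lists. Here too the noise was independent between genes. How often the rule picks out unchanged lists whose genes vary together is not shown.

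The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 RPKM, libraries rescaled to 1 total, quantile normalization, limma without the trend, differences centred on their median, 1.5-fold and 4-fold rules, no tissue block, leaving out each tissue pair, an estimated correlation, no surgery term, sham libraries alone, and random lists that were not matched. The alternatives chosen after seeing the data were the rows as deposited, the fits without the stomach and duodenum pairs, the tissue differences without the library labelled sham duodenum, the stomach libraries scaled to their total without the 10 highest genes of either, the lists with an estimated correlation in these smaller fits, and the agreement between tissues without the stomach and duodenum pairs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.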

Results

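The transcriptomes of 5 parts of the mouse gut were compared after vertical sleeve gastrectomy (VSG) and after a sham operation. VSG is an operation for weight loss that removes about 80% of the stomach along its lateral side and leaves about 20% as a tube. In the sham operation the abdomen was opened and the stomach gently pressed. Male C57BL/6J mice 17 weeks old had eaten a high-fat diet for 13 weeks and were fasted overnight before tissues were taken. Stomach, duodenum, jejunum, ileum and colon each gave 1 VSG and 1 sham library, 10 in all, so differences within a tissue have no replicates and carry no p-value. The sham libraries held 79260603 recovered reads on genes in stomach, 41278506 in duodenum, 41647301 in jejunum, 49081422 in ileum and 42413189 in colon. The VSG libraries held 45404302, 68335983, 36036619, 39516546 and 37810854 in the same order. A few genes took much of the signal in sham stomach, where the 10 highest genes, led by Pgc, Clps and Pla2g1b, held 41.8% of all RPKM, against 13.1% in VSG stomach, led by Tff1, Gkn2 and Gkn1. All 95% intervals below are exact and cover counting error only.

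Tissue markers did not contradict the labels of 9 of the 10 libraries, although no list was made to separate duodenum from jejunum. The list of proximal small intestine genes had a median of 72.2 RPKM in VSG duodenum. In sham and VSG jejunum it was at 18.7 and 14.8 RPKM. The list of stomach identity genes had a median of 503 RPKM in sham stomach and 176 RPKM in VSG stomach, and at most 1.06 RPKM in the other libraries. VSG duodenum still held gastric transcripts, since the 9 of these genes kept there had a median of 85.3 RPKM and the list of gastric mucous genes one of 276 RPKM. The ileum identity list was highest in ileum, at 106 and 115 RPKM, and the colon identity list in colon, at 56.9 and 65.5 RPKM. The exception was the library labelled sham duodenum. Its median for the enterocyte brush border list, genes of sugar digestion and uptake, was 0.289 RPKM against 319 RPKM in VSG duodenum, while its median for the list of enteric neurons and glia was 38.6 RPKM against 1.12 RPKM. Directions within duodenum, and in fits over tissues that include duodenum, rest on that library.

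**Figure D1:**
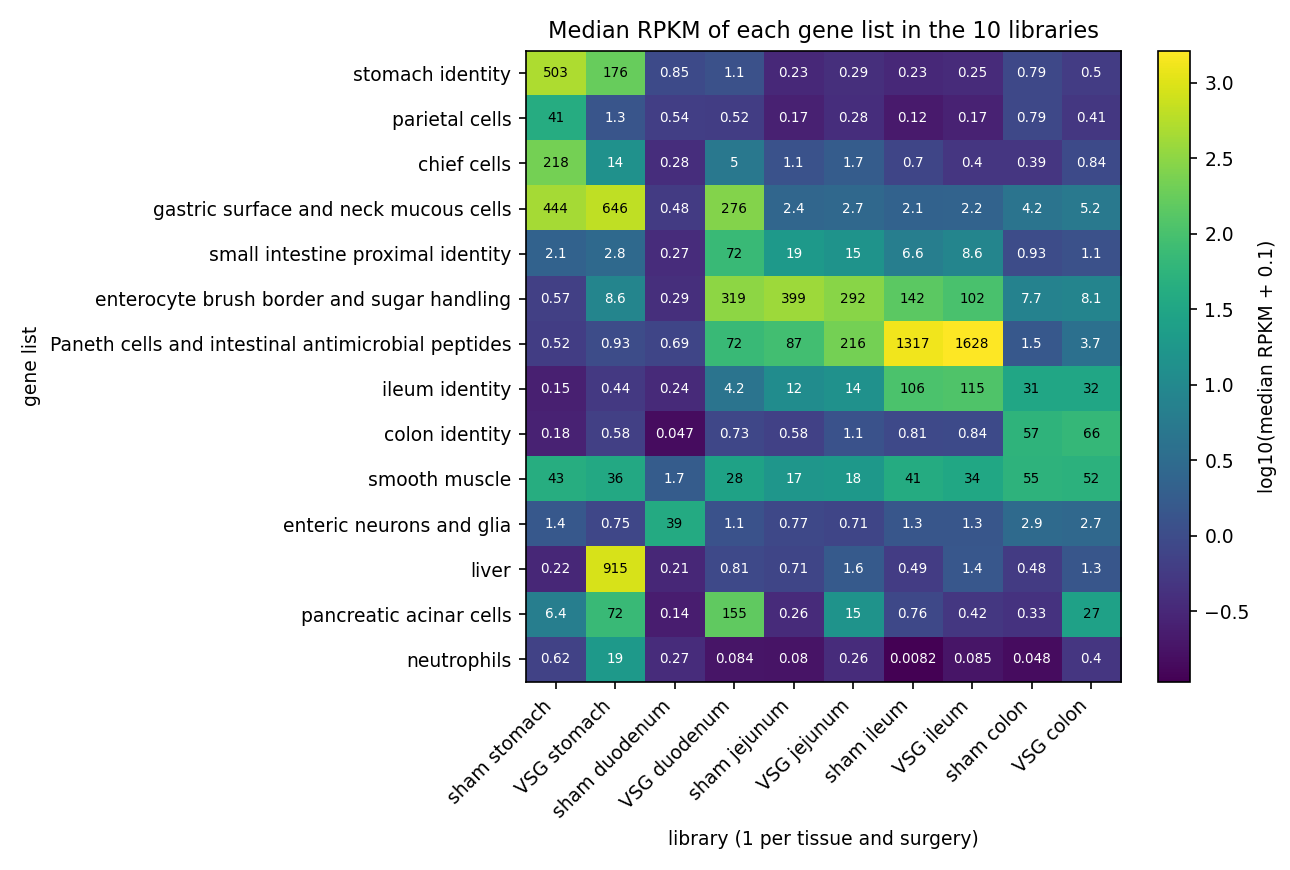
Median RPKM of 14 gene lists (vertical axis) in the 10 libraries (horizontal axis), with the colour giving log10(median RPKM + 0.1) and the number in each cell the median. The library labelled sham duodenum has neuronal transcripts (median 38.6 RPKM) and hardly any brush border transcripts (0.289 RPKM), and VSG stomach has liver transcripts at a median of 915 RPKM against 0.22 RPKM in sham stomach.

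To set the regional programme of the gut beside the operation, each tissue was compared with the other 4 over both surgeries. Stomach stood out through Gkn1 and Gkn2, gastrokines of surface mucous cells, Tff1, a secreted trefoil peptide, and Psca. Krt13, a keratin of the squamous forestomach, was the fifth (log2 9.54, SE 0.21). Ileum stood out through the Paneth cell defensins Defa33 (log2 10.85, SE 0.50), Defa32, Defa20 and Defa22 and through Fabp6, the ileal bile acid binding protein (10.14, SE 0.22). Colon stood out through Car1, a carbonic anhydrase (10.47, SE 0.30), Mptx1, Sval1, the posterior homeobox gene Hoxb13 and Tgm3. Jejunum had Dnase1, Slc5a12, a lactate transporter, Rab30, Mcoln3 and the hormone gene Cck, and duodenum had Cck, Scoc, Efr3b, Tnik and Cdip1. Of these, Scoc, Efr3b, Tnik and Cdip1 were highest in the library labelled sham duodenum and lost their calls with a pseudocount of 0.1. Scoc was at 97.2 RPKM there and 45.4 RPKM in VSG duodenum, and Efr3b in VSG duodenum (12.4 RPKM) lay below another tissue (21.1 RPKM). Cck was at 37.8 RPKM in the library labelled sham duodenum, where the hormone genes Gip and Sct were at 0.13 and 0.16 RPKM. Its duodenum call rests on that library too. In sham and VSG jejunum Cck was at 48.25 and 32.7 RPKM, below VSG duodenum (67.3 RPKM). By limma with Benjamini-Hochberg adjustment the adjusted p was 4.32e-05 for Krt13, 0.0236 for Gkn2 (log2 10.47, SE 1.70), 0.00309 for Defa33, 0.000194 for Fabp6 and 0.000259 for Car1. Each of these 5 was higher in both libraries of its tissue than in all 8 others. In total 921 of 14148 genes were higher in at least 1 tissue by this rule, with 562 for stomach, 343 for colon, 57 for ileum, 14 for jejunum and 9 for duodenum. The genes lower in a tissue numbered 284, 89, 32, 88 and 42 in the same order. A single library decided much of this, since 2896 genes were higher in at least 1 tissue without the library labelled sham duodenum, 480 of them for duodenum and 500 for jejunum.

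The VSG stomach library, from the organ that was operated on, held much less RNA of the acid and enzyme glands than the sham library and much more RNA of liver, leukocytes and connective tissue. Atp4a and Atp4b, the subunits of the gastric proton pump, were at 2093 RPKM in sham and 52.96 in VSG (39.5-fold lower, 95% interval 38.8 to 40.3) and at 2002 and 58.1 RPKM (34.4-fold lower, 33.4 to 35.5). Pgc, a pepsinogen, was at 92218 and 1376 RPKM (67.0-fold lower, 66.6 to 67.5), and Chia1, an acidic chitinase of chief cells, at 11208 and 14.1 RPKM (793-fold lower, 745 to 845). Alb, serum albumin, stood at 1.69 RPKM in sham and 5128 RPKM in VSG (3042-fold higher, 2700 to 3440). Of 13358 genes kept, 1725 were at least 2-fold higher and 527 at least 2-fold lower in VSG, and the log2 values of the libraries correlated at r = 0.770 across genes, which are not independent. Scaling both libraries to their total without the 10 highest genes of either, a choice made after seeing the data, moved the median of all genes by -0.314 and gave 1393 higher and 1155 lower.

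All 12 parietal cell genes kept were at least 2-fold lower, with a median log2 difference of -2.60, below every one of the random lists. Among them Trim50 was at 41.1 and 0.70 RPKM and Esrrg, a nuclear receptor of parietal cells, at 39.3 and 1.25 RPKM. Kcnq1, the potassium channel that serves acid secretion, was at 47.8 and 7.11 RPKM. Its partner Kcne2 had a log2 difference of -4.67. Chief cell genes had a median of -2.75, with 6 of 9 at least 2-fold lower, including Cblif, the gastric intrinsic factor (1726 and 113 RPKM), and the transcription factor Bhlha15 (19.5 and 2.04 RPKM). Gastric endocrine genes had a median of -1.77, with 5 of 8 lower. In that group Sst, somatostatin, was at 376 and 31.0 RPKM (12.1-fold lower) and Ghrl, ghrelin, at 1004 and 150 RPKM (6.68-fold lower). Chga was at 252 and 25.2 RPKM and Slc18a2 at 12.5 and 1.51 RPKM. Surface and neck mucous genes had a smaller median of -0.71, although the median of their levels was 444 RPKM in sham and 645.5 RPKM in VSG. Psca was at 4459 and 1082 RPKM, Muc5ac, the surface mucin, at 503 and 176, and Gkn1 at 12517 and 6181, while Gkn3 was higher, at 384 and 1201 RPKM. Smooth muscle genes had a median of -0.72, with Myh11 at 187 and 64.7 RPKM, and oxidative phosphorylation genes one of -0.48. The remaining genes of the 10 lowest were the pancreatic-type lipases and cofactors Pla2g1b (18550 and 52.6 RPKM, 353-fold lower), Clps (41858 and 263 RPKM, 159-fold lower) and Pnliprp2, with Pdia2 and Smim38.

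**Figure D2:**
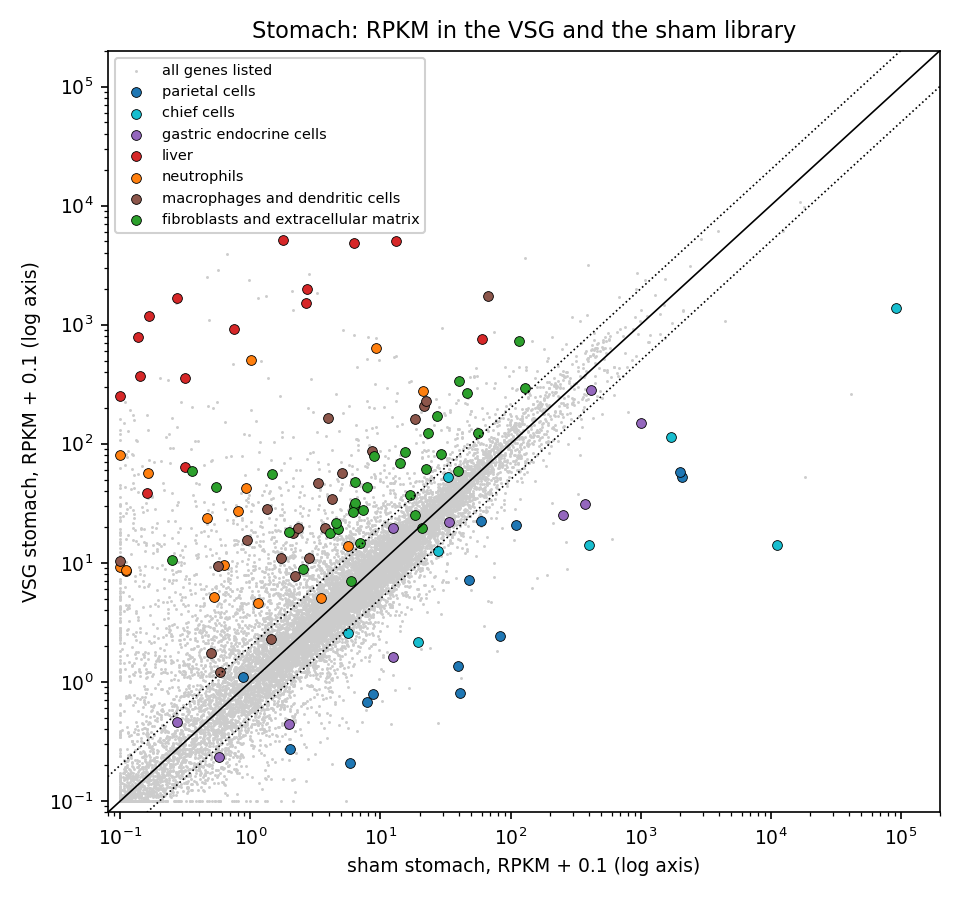
RPKM + 0.1 of each gene in the sham (horizontal axis) and VSG (vertical axis) stomach library on log axes, 1 library each, with 7 gene lists in colour, a solid line at equality and dotted lines at 2-fold. Most parietal and chief cell genes lie below the lines (median log2 differences -2.60 and -2.75), and most liver, neutrophil, macrophage and connective tissue genes lie above them (8.73, 3.48, 3.07 and 2.11).

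Liver transcripts had the largest median difference of all lists in stomach. All 15 genes of the liver list were at least 2-fold higher (median 8.73), and the 10 largest differences, most of them in genes of plasma proteins or acute phase reactants, were those of Hpx (0.56 and 3938 RPKM), Saa2, Alb, Saa1, Mup20, Saa3, Lcn2, Fgb, Apoa2 and Orm2. Hp, haptoglobin, was at 6.11 and 4885 RPKM and Cyp2e1, a hepatic cytochrome P450, at 0.65 and 915 RPKM. Pancreatic acinar genes were higher too, at a median of 2.72 with 18 of 26 at least 2-fold higher, among them the digestive protease genes Ctrb1 (0.63 and 466 RPKM) and Cpa1 (0.081 and 70.4 RPKM), while Clps of the same list was lower.

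Genes of leukocytes, cytokines and connective tissue were higher in the same library, which held the liver RNA. Neutrophil genes had a median of 3.48 with 15 of 16 at least 2-fold higher. S100a8 (0.91 and 504 RPKM) and S100a9 (9.12 and 637 RPKM), which encode the subunits of calprotectin, were among them. The granule gene Ngp was at 0 and 80.4 RPKM and Camp, a cathelicidin, at 0.064 and 57.1 RPKM. Macrophage and dendritic cell genes had a median of 3.07 with 19 of 21 higher, such as Cd14, the lipopolysaccharide coreceptor (3.88 and 165 RPKM), Cd68 (4.97 and 57.0) and Trem2 (1.23 and 28.1). Cytokine and acute phase genes had a median of 3.20 (23 of 26 higher), with Cxcl5 at 0.28 and 105 RPKM. All 11 genes of MHC class II presentation were higher (median 2.31), including Cd74, the invariant chain (147 and 733 RPKM). So were 11 of 12 T and NK cell genes (1.52), 9 of 10 B and plasma cell genes (2.14) and 14 of 37 interferon response genes (0.51). Connective tissue genes had a median of 2.11 with 28 of 33 higher. Among them were the matrix metalloproteinase genes Mmp3 (0.26 and 59.0 RPKM) and Mmp13 (0.44 and 43.0), their inhibitor Timp1 (1.36 and 55.8) and the collagen gene Col1a1 (39.9 and 339). Sterol transport genes were higher as well (1.49, 10 of 13), led by Apoe (129 and 3666 RPKM) and Lcat (0.55 and 77.7), both abundant in liver and read beside the liver list above. Squamous epithelium genes went both ways around a median of -0.21, with the wound keratins Krt6a (26.4 and 236 RPKM), Krt6b and Krt16 higher and Krt15 lower (29.0 and 11.4). Of 46 lists, 22 lay above and 11 below the central range of random lists. Rescaling libraries to 1 total moved the median of all genes by 0.167 and brought the squamous list to -0.005, and the design holds no sham sample of the part of stomach that VSG leaves.

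In duodenum the question of what VSG changed rests on the library labelled sham duodenum, which held neural RNA and hardly any intestinal RNA. Genes of neurons and glia were far higher there than in VSG duodenum. Nefl, a neurofilament subunit, was at 347 and 0.41 RPKM (851-fold lower in VSG, 642 to 1155) and Gfap, the astrocyte filament, at 198 and 0.30 RPKM (652-fold lower, 518 to 831). Snap25, a synaptic fusion protein, was at 498 and 3.37 RPKM and Ptgds at 360 and 0.042 RPKM. Nap1l5, Tmem130, Meg3, Mlc1, Vsnl1, Gpm6a and Snhg11 made up the rest of the 10 lowest. Enterocyte genes were near 0 in the library labelled sham duodenum and abundant in VSG duodenum. Fabp1, a fatty acid binding protein, was at 2.45 and 7109 RPKM and Apoa4, a lipoprotein component, at 5.30 and 10034. The alkaline phosphatase genes Akp3 (0.37 and 3175 RPKM) and Alpi (0.55 and 3210), with Prap1, Tff2, Reg1, Fabp2, Rbp2 and Gsta1, completed the 10 highest. Smooth muscle genes were also higher in VSG duodenum (median 2.61, 14 of 20 at least 2-fold higher), with Des, desmin, at 0.58 and 118 RPKM.

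By group, brush border genes had a median log2 difference of 7.49 (20 of 20 higher, Sis, sucrase-isomaltase, at 0.29 and 1228 RPKM) and mucous genes 7.16 (12 of 12). Pancreatic acinar genes had 6.66 (26 of 26, Ctrb1 at 0.37 and 764 RPKM), goblet cell genes 6.14 (8 of 10, Tff3 at 0.91 and 1197 RPKM), and Paneth cell genes 5.64 (22 of 22). Genes of enteric neurons and glia had a median of -4.46 (22 of 23 lower) and red blood cell genes of -2.33. Of 14452 genes kept, 3974 were at least 2-fold higher and 4034 lower in VSG, and r was 0.309 across genes. After rescaling to 1 total, which moved the median of all genes by -0.832, the split was 2349 higher and 6751 lower.

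In jejunum the VSG library had more transcripts of pancreatic enzymes and of antimicrobial defence and fewer of detoxifying enzymes. Ctrb1, chymotrypsinogen, was at 0.51 RPKM in sham and 75.4 RPKM in VSG (149-fold higher, 94.1 to 252). Reg3b, a bactericidal lectin, was at 105 and 1980 RPKM (18.9-fold higher, 18.2 to 19.6) and Mptx2, a mucosal pentraxin made by Paneth cells, at 2.77 and 131 RPKM (47.5-fold higher, 37.9 to 60.3). Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, had 1270 reads in sham (11.4 RPKM) and 0 in VSG, at least 396-fold lower against a floor of 3 reads. Akp3, an intestinal alkaline phosphatase, was at 223 and 36.0 RPKM (6.18-fold lower, 5.98 to 6.39).

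The 10 highest genes held 7 more pancreatic enzyme genes, namely Prss2, Amy2a5 (0.78 and 50.8 RPKM), Amy2a3, Try4, Try5, Cela2a (0.22 and 27.9 RPKM) and Cela3b. The acinar list had a median of 2.97 (21 of 25 at least 2-fold higher). Paneth cell and antimicrobial genes had a median of 1.16, with 18 of 22 at least 2-fold higher, including Reg3g (50.1 and 645 RPKM), the defensin gene Defa21 (15.5 and 164) and Mmp7, the protease that activates defensins (20.6 and 68.4). Cytokine and acute phase genes had a median of 1.395 (8 of 12 at least 2-fold higher), with Saa3 at 0.21 and 9.13 RPKM. Lcn2, a siderophore-binding defence protein, was at 0.82 and 7.09 RPKM and Duox2, an epithelial hydrogen peroxide source, at 0.16 and 2.02 RPKM. Macrophage genes were above 0 in 16 of 17 cases (median 0.57), with Lyz2 at 163 and 373 RPKM. All 9 MHC class II genes were above 0 without reaching 2-fold (0.50, Cd74 at 241 and 366 RPKM). Adipocyte genes had a median of 0.25, with 9 of 14 above 0. Of these, 3 were at least 2-fold higher, namely Cfd, the complement protease adipsin (0.23 and 4.95 RPKM, 21.4-fold higher, 11.4 to 45.2), Car3 (0.89 and 5.92) and Adipoq, adiponectin (0.40 and 2.18).

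Genes of xenobiotic metabolism had a median of -0.63, with 5 of 28 at least 2-fold lower and 1 above 0. Within this list Aldh1a1, a retinaldehyde dehydrogenase, was at 505 and 245 RPKM and the glutathione transferase gene Gsta1 at 1286 and 637. Ces1f, a carboxylesterase gene, was at 156 and 68.7 RPKM. The fatty acid hydroxylase genes Cyp4a10 (47.1 and 19.6 RPKM) and Cyp4a32, with Slc16a9, Otop3, Pdx1, G0s2 and Acta1, completed the lowest genes. Brush border genes had a median of -0.37, with Pck1, a gluconeogenic enzyme, at 53.7 and 23.4 RPKM. Fatty acid oxidation genes had -0.34, fat absorption genes -0.29 and oxidative phosphorylation genes -0.27. Genes of proximal small intestine identity were lower as well, with a median of -0.39 (percentile 0.03, 1 of 12 above 0). Of 11674 genes kept, 89 were at least 2-fold higher and 35 lower (r = 0.984 across genes). Of 42 lists, 12 lay above and 9 below the central range. Rescaling moved the median of all genes by 0.125, gave 101 higher and 22 lower, and left the xenobiotic list at -0.48 and the brush border list at -0.23. It brought fatty acid oxidation genes to -0.19, fat absorption genes to -0.14, oxidative phosphorylation genes to -0.12 and genes of proximal small intestine identity to -0.25.

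Ileum had the fewest genes at 2-fold. Pla2g4c, a cytosolic phospholipase, was at 1.71 RPKM in sham and 39.6 in VSG (23.2-fold higher, 20.6 to 26.1). S100g, an intestinal calcium carrier, was at 1.15 and 12.4 RPKM (10.8-fold higher, 7.81 to 15.2) and Mptx2 at 53.7 and 268 RPKM (4.99-fold higher, 4.74 to 5.25). Fgf15, the hormone by which ileum restrains bile acid synthesis in liver, was at 17.9 and 54.4 RPKM (3.04-fold higher, 2.87 to 3.22). Saa1 was at 29.8 and 8.66 RPKM (3.44-fold lower, 2.99 to 3.98) and Adh1, an alcohol dehydrogenase, at 150 and 55.3 RPKM (2.71-fold lower, 2.60 to 2.82).

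Other genes among the 10 highest were Cfd (2.15 and 9.67 RPKM, 4.49-fold higher, 3.64 to 5.57) and Duoxa2, the maturation factor of Duox2 (14.2 and 42.4 RPKM, 2.98-fold higher, 2.78 to 3.20). The others were Mptx1, the cornified envelope genes Sprr2b and Sprr2a1, and Slc30a10, a manganese exporter. The lowest included the xenobiotic genes Cyp2b10 (33.4 and 14.7 RPKM), Ces1f (39.8 and 18.3), Gstm3, Gstm6 and Cyp3a11 (31.5 and 16.9), with Nat8f5. As groups, xenobiotic genes had a median of -0.29 (3 of 28 at least 2-fold lower), and brush border genes -0.29 (Lct, lactase, at 163 and 111 RPKM). B and plasma cell genes had -0.41 (2 of 15 above 0), smooth muscle genes -0.36 (Myh11 at 94.7 and 60.1) and circadian clock genes -0.24 (Per1 at 7.79 and 4.28, Per2 at 15.5 and 9.73). Paneth cell genes had a median of 0.38, with 21 of 23 above 0 and none at 2-fold (Ang4, a microbicidal angiogenin, at 441 and 706 RPKM). Macrophage genes had 0.25 (17 of 19 above 0) and cholesterol synthesis genes 0.22 (23 of 24 above 0). Of 12195 genes kept, 18 were at least 2-fold higher and 15 lower (r = 0.994 across genes), against 15 and 19 after rescaling. Of 41 lists, 14 lay above and 10 below the central range.

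In colon the largest differences were again pancreatic enzyme transcripts, higher in VSG. Ctrb1 was at 0.95 RPKM in sham and 143 RPKM in VSG and Amy2a5, an amylase, at 0.63 and 83.4 RPKM. All 10 of the highest genes were of this kind, with Prss2, Cela2a, Cela3b, Try4, Try5, Pnlip, Amy2a2 and Amy2a3 (acinar list median 3.67, 20 of 26 at least 2-fold higher). Genes of fatty acid oxidation were all above 0 (23 of 23, median 0.31, 5 at least 2-fold higher). Pdk4, a kinase that shuts down pyruvate dehydrogenase, was at 2.86 and 12.9 RPKM (4.53-fold higher) and Angptl4, an inhibitor of lipoprotein lipase, at 3.43 and 9.16. The transcription factor gene Creb3l3 was at 6.48 and 17.9 RPKM and Acaa1b, a peroxisomal thiolase, at 23.5 and 54.2. Of 8 calcium and vitamin D genes, 2 were at least 2-fold higher, S100g at 15.2 and 58.7 RPKM (3.86-fold, 3.48 to 4.29) and Trpv6, the apical calcium channel, at 0.50 and 3.21 RPKM. That list as a whole lay inside the central range (median 0.08, percentile 90.12, 5 of 8 above 0). Reg3b was lower here, at 116 and 43.6 RPKM (2.66-fold lower, 2.49 to 2.84), as was Reg3g, at 30.7 and 14.5 RPKM.

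Adipocyte genes had a median of 0.45, with Cfd at 4.11 and 25.3 RPKM (6.16-fold higher, 5.27 to 7.23) and Car3 at 12.05 and 26.9 RPKM. Fat absorption genes had a median of 0.45 (3 of 22 at least 2-fold higher, Apoa1 at 11.3 and 26.6 RPKM) and xenobiotic genes 0.25 (21 of 24 above 0). Genes of proximal small intestine identity were higher in the same pair (0.52, 6 of 7 above 0), with 3 at least 2-fold higher, S100g, Trpv6 and Apoa4. Below the range lay B and plasma cell genes (-0.35, 2 of 14 above 0, Jchain at 172 and 122 RPKM) and genes of enteric neurons and glia (-0.25, 3 of 20 above 0, the neuropeptide gene Vip at 27.1 and 17.2). Cell cycle genes lay there too (-0.14, 2 of 29 above 0, the mitotic kinase gene Aurkb at 8.997 and 6.17). Pgc, Angptl7, Pla2g1b, Cd79b, Cyp2c69, Grem1 and Scg5 were the other genes of the 10 lowest, of which Pgc (37.1 and 15.05 RPKM) was at least 2-fold lower. Of 12963 genes kept, 56 were at least 2-fold higher and 6 lower (r = 0.989 across genes), and 17 lists of 43 lay above and 9 below the central range.

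Changes shared by all 5 tissues were asked for with the tissue pairs as replicates. Among the genes with the smallest p that were higher in 5 of 5 tissues were Duoxa2 (log2 1.08, SE 0.15), Duox2 (0.93, SE 0.14), Cd177, a neutrophil surface protein, Cfd (1.57, SE 0.34), Aplnr, Slpi, a secreted antiprotease, Gsdmc4, Car3 and C1rb. Among those lower in 5 of 5 were Ctxn3, Cers4, Rgcc, Ccdc137, Cacna1h, Coprs, Tigar, Gpatch11 and Tm2d3. None passed. By limma with Benjamini-Hochberg adjustment 0 of 14148 genes were called, 137 had an unadjusted p under 0.05, and the smallest adjusted p was 0.702. In the small intestine alone limma called 0 of 13577 genes, with 19 at an unadjusted p under 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.757. Its leading genes, in 3 of 3 segments, included C3 (1.33, SE 0.22), Duoxa2, Duox2, Defa-ps1, Gsdmc4, Defa25, Defa28, Aplnr and Defa40 on the higher side. On the lower side they were Rhbdl1, Apbb3, Gpr137, H4c8, Cuedc1, Gstm1, Iqcc, Efr3b, Ufsp1 and Emc9. The duodenum direction of these genes on both sides also rests on the library labelled sham duodenum.

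The pair that holds the library labelled sham duodenum decided the small intestine result. Without it, an alternative fixed before the data were examined, jejunum and ileum together gave 107 called genes of 12019, 43 that rose and 64 that fell, each in 2 of 2 tissues, with 1348 at an unadjusted p under 0.05 and 1 residual degree of freedom. The error of this fit comes only from how far the changes of jejunum and ileum differ. If both segments came from the same animals, which the labels leave open, a difference between animals cannot be told apart from surgery. Cfd, adipsin, a gene of the adipocyte list, led the genes that rose (log2 2.01, SE 0.14, limma with Benjamini-Hochberg adjusted p 0.000143). With it rose Duoxa2 (1.42, SE 0.10), Duox2 (1.18), Mptx2 (3.72, SE 0.44), the complement gene C3 (1.33), S100a9 (1.49), Gsdmc2, Gsdmc3 and Gsdmc4 of the pore-forming gasdermin family, and Slc34a2, a phosphate transporter. The genes that fell were led by Cyp1a1 (-2.93, SE 0.25, limma with Benjamini-Hochberg adjusted p 0.000319) and Ces1f (-1.13, SE 0.12, 0.000963), both of the xenobiotic list. With them fell Cyp2b10 (-1.05), Ces1e (-0.90), Gsta3 (-0.87), Gstm3 (-0.94), Cyp3a11 (-0.91), Slc28a1, a nucleoside transporter, and Acta1. Of the 15 adipocyte genes 2 rose over all genes tested, Cfd and Car3 (1.32), and 5 rose and 1 fell when adjusted over the list alone (median 0.11). Pancreatic acinar genes had a median of 1.501 in this fit, with 1 of 22 up over all genes tested and 19 adjusted over the list alone. Jejunum carried it, with a median of 2.97 within that tissue against -0.10 in ileum, where 3 of the 10 acinar genes kept were above 0. Of 28 xenobiotic genes 11 fell over all genes tested and 16 when adjusted over the list alone. Genes of proximal small intestine identity were lower in the same pairs, with medians of -0.39 in jejunum and -0.26 in ileum (4 of 11 above 0). Of the Paneth cell genes 3 rose over all genes tested and 15 when adjusted over the list alone, where 1 fell. The camera test gave adjusted p = 1.96e-19 for the xenobiotic list (median -0.47) and 2.00e-14 for the Paneth list (0.75), and adjusted p = 0.914 for both with an estimated correlation. That setting cannot weigh these lists, because the correlation was estimated from 1 residual degree of freedom and every list lay at 0.914 or more.

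**Figure D3:**
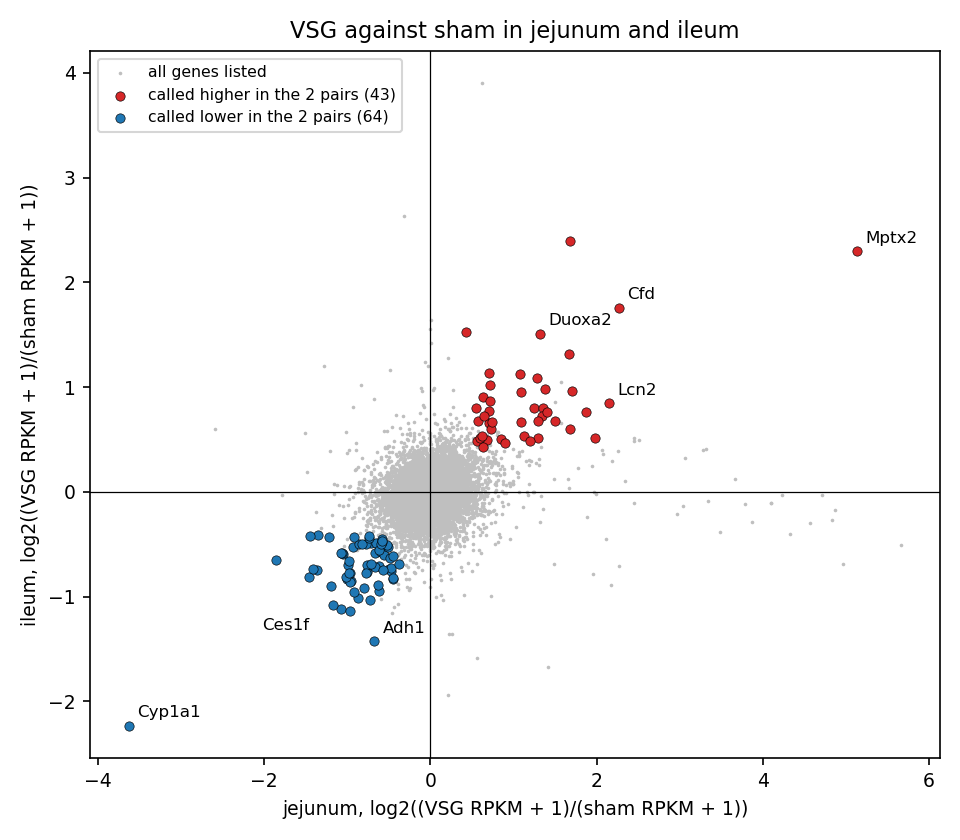
Log2((VSG RPKM + 1)/(sham RPKM + 1)) of each gene in jejunum (horizontal axis) and ileum (vertical axis), 1 library per surgery and tissue, with the 43 genes called higher in red and the 64 called lower in blue. Cfd and Mptx2 lie far to the upper right and Cyp1a1 to the lower left (fitted log2 differences 2.01, 3.72 and -2.93).

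With colon added to jejunum and ileum, a fit chosen after seeing the data, 2 of 12608 genes rose, each in 3 of 3 tissues. They were Cfd (log2 2.13, SE 0.13, limma with Benjamini-Hochberg adjusted p 0.00868) and S100a9 (1.502, SE 0.10, adjusted p 0.0130). C3 (1.26), Duoxa2 (1.20), Duox2 (1.04) and S100a8 (1.32) followed at an adjusted p of 0.118 by limma with Benjamini-Hochberg adjustment, each higher in 3 of 3 tissues, and did not pass. Per1 (-0.52), a clock gene, was lower in 3 of 3 tissues at an adjusted p of 0.483 in the same limma fit and did not pass either.

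Over all 5 tissues camera called 28 of 48 lists, 26 up and 2 down, and each call was lost with an estimated correlation between genes, where the smallest adjusted p was 0.553. Without the duodenum pair 27 lists were called, 18 up and 9 down, and 0 with an estimated correlation. In the camera test over all 5 tissues pancreatic acinar genes led (median log2 3.07, adjusted p = 7.80e-18, 15 of 26 up adjusted over the list alone and 0 over all genes). Next came Paneth cell and antimicrobial genes (1.66, adjusted p = 1.38e-10), interferon response genes (0.61, 1.23e-09), cytokine and acute phase genes (1.00, 2.23e-09), ribosomal protein genes (0.35, 5.17e-09), connective tissue genes (0.64, 1.79e-08) and macrophage genes (0.92, 3.09e-08). The lists called down were parietal cells (-0.84, adjusted p = 0.0107) and enteric neurons and glia (-1.04, adjusted p = 2.77e-07), of which the latter contains the neural transcripts of the library labelled sham duodenum. Medians of lists called up draw on that pair too, where acinar genes had a median of 6.66, Paneth cell genes 5.64 and ribosomal protein genes 1.37. At the preset correlation the acinar, Paneth and ribosomal lists were also called up without that pair. Xenobiotic genes were called up with it (median 0.97, camera adjusted p = 0.00248) and down without it (-0.12, adjusted p = 0.0399). Brush border genes went from 1.69 (adjusted p = 5.34e-05) to 0.13 (adjusted p = 0.677). Gastric mucous, goblet cell, cell cycle, fatty acid oxidation and bile acid lists were called up only with it. So were the amino acid transport, iron and vitamin, and B and plasma cell lists. In the fit over all 5 tissues fatty acid synthesis genes had a median of 0.13 and a mean of 0.18 while their test pointed down. Squamous epithelium genes (median -0.07, mean 0.07) and enteroendocrine transcription factor genes (median -0.10, mean 0.05) differed in sign between median and mean. In jejunum, ileum and colon alone, 21 lists were called, 12 up and 9 down. Markers of other organs were among those up, with pancreatic acinar genes first (median 2.20, adjusted p = 1.25e-20, 20 up adjusted over the list alone and 0 over all genes) and liver genes as well (0.47, 7.41e-06, 4 up adjusted over the list alone and 0 over all genes). Also up were macrophage genes (median 0.32, adjusted p = 7.33e-16, 10 up adjusted over the list alone and 0 over all genes), Paneth cell genes (0.69, 5.10e-18, 16 up and 1 down adjusted over the list alone and 0 over all genes) and adipocyte genes (0.17, 1.43e-06, 7 up adjusted over the list alone and 1 over all genes). None was called with an estimated correlation, where the adjusted p was 0.561 or more. That fit leaves 2 residual degrees of freedom, and lists planted in it were not simulated, so this loss is a weak check.

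Gut hormone genes, which VSG is studied for, differed by tissue. The list of enteroendocrine hormone and granule genes lay above the central range in ileum (median 0.11, 13 of 21 above 0). It lay below that range in stomach (-1.05, 5 of 19 above 0) and colon (-0.13, 5 of 20 above 0), and inside it in jejunum (percentile 9.31). Gcg, which encodes glucagon-like peptide 1, was at 34.5 RPKM in sham and 52.3 in VSG ileum (ratio 1.51, 1.42 to 1.61), at 18.7 and 22.3 in jejunum, and at 65.0 and 62.9 in colon (0.968, 0.918 to 1.02), where the difference was not detectable at this depth. Nts, neurotensin, was at 86.9 and 115 RPKM in ileum (1.32, 1.27 to 1.37) and 16.9 and 12.7 in colon, and Pyy, peptide YY, at 38.3 and 49.4 in ileum and 107 and 125 in colon. Jejunum had lower values in VSG for Gip (130 and 97.2 RPKM), Cck (48.3 and 32.7) and Sct, secretin (52.6 and 33.9). In stomach Gast, gastrin, was at 419 and 280 RPKM (0.670, 0.650 to 0.690), a smaller difference than those of Ghrl and Sst above, and Sst differed little in ileum (54.8 and 55.3) and colon (33.6 and 34.1). Of the bile acid genes in ileum other than Fgf15, Fabp6 was at 4365 and 4449 RPKM and Slc10a2, the apical bile acid transporter, at 106 and 110 RPKM. Nr0b2, a nuclear receptor induced by bile acids, was at 0.47 and 0.94 RPKM in ileum (ratio 2.02, 1.21 to 3.44) and 10.4 and 4.79 RPKM in jejunum.

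The differences of the 5 tissues were also compared gene by gene. Across the 14148 genes, which are not independent, the Pearson correlation of the log2 differences lay between -0.08 and 0.31 over 10 pairs of tissues, with a median of 0.165. Of these pairs, 4 use the library labelled sham duodenum, among them the lowest, and without stomach and duodenum, a choice made after seeing the data, the median was 0.231. The highest was between jejunum and colon (0.31), where Spearman's rho was -0.14, and jejunum and ileum had 0.23 by both measures.

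In GRCm38 coordinates, Atp4a (Entrez 11944) lies on chromosome 7 from 30712209 to 30725534 and Chia1 (81600) on chromosome 3 from 106113382 to 106132118. Alb (11657) lies on chromosome 5 from 90460870 to 90476602 and Cfd (11537) on chromosome 10 from 79890853 to 79892655. S100a9 (20202) lies on chromosome 3 from 90692630 to 90695721 and Fgf15 (14170) on chromosome 7 from 144896532 to 144900953. Cyp1a1 (13076) lies on chromosome 9 from 57687928 to 57703824 and Mptx2 (100504232) on chromosome 1 from 173274461 to 173277756. Ctrb1 (66473) lies on chromosome 8 from 111686510 to 111691010, Gfap (14580) on chromosome 11 from 102887336 to 102897200 and Pla2g4c (232889) on chromosome 7 from 13311507 to 13360674.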

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

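The tests of central nervous system markers, of hepatocyte markers and of the correlation of acinar genes were fixed before their results were seen; the tests of smooth muscle, brush border, the highest acinar library, the gland and mucous lists, scaling and squamous genes, the correlation without Sycn, and the test of the stomach against the other tissues were chosen after the result was seen.

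The change in stomach was tested against that in the other tissues, with a single stomach pair on 1 side, so that the spread comes from the other pairs and the stomach pair is assumed to vary like them. Its log2 differences had an SD of 1.17 across genes, against 0.33, 0.20 and 0.26 in jejunum, ileum and colon. The calls therefore describe how far these 2 stomach libraries differ and do not replicate the stomach change. By limma with Benjamini-Hochberg adjustment 241 of 14148 genes differed between the stomach pair and the 4 intestinal pairs (224 more positive in stomach, 17 more negative, and 1129 at an unadjusted p under 0.05). Against the jejunum, ileum and colon pairs alone the number was 3442 of 13350 (2104 more positive, 1338 more negative, and 5309 at an unadjusted p under 0.05). Hepatocyte genes led this set, with the smallest p for Mup3 (log2 difference of changes 7.78, SE 0.14, limma with Benjamini-Hochberg adjusted p 1.18e-05), Hrg, Apoh and Kng1, and 15 of 15 liver genes were more positive in stomach, in the VSG library that held liver RNA. So were 14 of 14 neutrophil, 19 of 20 macrophage and 30 of 33 connective tissue genes, while 10 of 11 parietal and 7 of 9 chief cell genes were more negative. Further examples, chosen after their values were seen, were the proton pump gene Atp4a (log2 difference of changes -5.09, SE 0.20, limma with Benjamini-Hochberg adjusted p 4.43e-05), the neutrophil gene S100a8 (6.73, SE 0.31, adjusted p 8.72e-05) and the matrix protease gene Mmp3 (5.53, SE 0.22, adjusted p 4.39e-05), each with the stomach value beyond those of all 3 other tissues.

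The library labelled sham duodenum is the first pattern, with neural transcripts in place of intestinal ones. A duodenal wall rich in muscle and nerve plexus is argued against, since the median of the smooth muscle list was 0.0988 of the lowest of the other 9 libraries, and so is duodenum mixed with neural tissue, since the median of the brush border list was 0.284% of that of the lowest VSG library of small intestine. Of 12 markers of the central nervous system, 10 were at 5 RPKM or more in this library and below 1 RPKM in the other 9, such as the glutamate transporter gene Slc17a6 (50.2 RPKM) and the GABA enzyme gene Gad1 (34.6), and the exceptions were Opalin at 3.47 RPKM and Slc1a2, at 84.8 RPKM here but 4.13 RPKM in VSG stomach. A wrong label or a wrong sample of central nervous system tissue is therefore a candidate explanation. No effect of the operation on duodenum can be read from this pair, and a biological difference was not tested.

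Liver and pancreatic transcripts in VSG libraries are the second pattern. Reads of another library of the series assigned to VSG colon are argued against for the acinar genes. The highest library of each gene, in most cases VSG duodenum, exceeded VSG colon by a median of only 6.09-fold over the 19 acinar genes. This was not examined for the other VSG libraries. RNA from liver in VSG stomach may account for the liver genes, since 14 of 15 hepatocyte markers were at 5 RPKM or more and 4-fold above sham, Alb reached 5128 RPKM and Apoa2 1665 RPKM, and the exception was Cyp2f2 (29.7 and 24.9 RPKM). RNA from pancreas and expression in the gut wall cannot be told apart for the acinar genes, because the lowest correlation between VSG libraries was 0.766, between the values set for either outcome, and it was 0.981 without Sycn, a gene that sham colon itself has at 845 RPKM. Adhesion of liver or pancreas to the operated gut, carry-over at dissection, and an effect of the operation stay open and were not tested.

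The lower gland transcripts of VSG stomach are the third pattern. One lower share of the gastric epithelium, surface included, is argued against. The middle ranges of the parietal and mucous lists lay apart by 1.46 on the log2 scale. Scaling to the total without the 10 highest genes of either library moved the median of all genes by -0.314. It left the parietal list at -2.86. The 10 highest genes held 41.8% of all RPKM in sham stomach and 13.1% in VSG stomach. Leaving them out could therefore only lower the differences, so this result was fixed in advance and is no test of scaling. Their larger share in sham lowers the other sham values, the opposite of the pattern. Whether a single lower share of gland tissue below the surface accounts for the parietal, chief and endocrine genes cannot be decided from these lists. The middle ranges of these 3 lists share a width of 0.423, but each range is wide. They ran from -4.64 to -2.44 (parietal), -4.75 to -0.995 (chief) and -2.87 to -0.597 (endocrine). Genes of the same list thus changed by different amounts, and an overlap does not show that the lists fell alike. The operation removes about 80% of the stomach, so the part sampled and an effect on the cells that remain cannot be told apart. The median of the squamous list, -0.205, does not decide this, because no sham sample of the part left by the operation was analysed here.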

How the results depend on the processing

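The fits without the stomach and duodenum pairs, without the library labelled sham duodenum, with the rows as deposited and with stomach scaled without its highest genes were tests chosen after the result was seen. The single genes were named for large differences or small p, so a kept direction was nearly fixed in advance. Of 1095 values of 165 such genes under the alternatives other than the rows as deposited, all 1095 kept their direction and 0 reversed. Of these, 883 stayed within their counting interval or on their side of the threshold and 182 with no test moved beyond that interval, while 13 passed a threshold they had missed and 17 no longer passed it, among the latter the tissue genes Scoc, Efr3b, Tnik, Cdip1 and Mcoln3. The counts and list results moved in 49 cases, were the same in 117, rose from 0 in 2 and fell to 0 in 3. The cause was not tested unless a lower or higher threshold, fewer genes or other libraries give it by construction.

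The number of called genes over 5 tissues was 0 under each alternative fixed before the data were examined, 0 to 0 when each pair was left out (leave-one-out), and 2 without the stomach and duodenum pairs. For the small intestine leave-one-out gave 0 to 107 genes, with 107 without the duodenum pair. The 28 lists ranged from 24 to 32 in leave-one-out fits, and were 0 with the correlation estimated, 0 also without the duodenum pair and 0 without the stomach and duodenum pairs. The last of these fits leaves only 2 residual degrees of freedom for that estimate.

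For the within-tissue counts, in the order stomach, duodenum, jejunum, ileum and colon where all are given, a pseudocount of 5 gave 1243, 5102, 63, 10 and 29, a mean of at least 5 RPKM 1458, 5279, 68, 19 and 35, and the 4-fold rule 917, 4172, 37, 5 and 24. The 1.5-fold rule gave 4074 in stomach, 461 in jejunum, 181 in ileum and 164 in colon, and a pseudocount of 0.1 gave 203 in jejunum, 77 in ileum and 96 in colon. With the rows as deposited the counts were similar but the intestinal names were not, with 4703 of 8008 names shared in duodenum, 49 of 124 in jejunum, 9 of 33 in ileum and 20 of 62 in colon. In stomach, whose columns were not moved, 2252 of 2252 names were shared.

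For the tissue differences, a pseudocount of 0.1 gave 3 genes for duodenum and 25 for ileum, a mean of at least 5 RPKM 568 in all, 306 for stomach and 5 for duodenum, rescaling 542 and quantile normalization 224 for colon, and no surgery term 18 for duodenum and 36 for jejunum. In the order total, stomach, duodenum, jejunum, ileum and colon, the rows as deposited gave 5337, 3471, 510, 346, 369 and 1407, leaving out the library labelled sham duodenum 2896, 1209, 480, 500, 407 and 1049, and the sham libraries alone at 4-fold with no test 1669, 316, 1162, 51, 36 and 104.

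Replicate numbers gave no pairing because each group has 1 library. The surgery fits over tissues pair the libraries by tissue, and without this block the counts over 5 tissues were 0 genes and 30 lists. The tissue differences hold surgery as a term and no tissue block. At depths of 36036619 to 79260603 reads, counting error limits the genes near the floor, such as Cyp1a1 at 0 reads in VSG jejunum, and the lack of replicates limits all others.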

Other observations

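The counts of splits and of exchanged labels below are tests chosen after the result was seen, and the genes named were chosen after their values were seen.

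Some single genes were higher in VSG in each of jejunum, ileum and colon, while the list of B and plasma cells lay below the central range of random lists in ileum and colon (medians -0.41 and -0.35) and that of T and NK cells in ileum (-0.17). In jejunum both lists lay above it, at 0.29 and 0.36. Cfd, adipsin, was higher in VSG by 21.4-fold in jejunum, 4.49-fold in ileum and 6.16-fold in colon, C3, the central complement protein, by 3.62-fold, 2.02-fold and 2.21-fold, and Car3, a carbonic anhydrase of fat and muscle, by 6.65-fold, 1.81-fold and 2.23-fold. The calprotectin subunit gene S100a9 was higher by 31.5-fold (8.35 to 266), 26.9-fold (7.00 to 229.6) and 6.16-fold, from 2 sham reads in each of jejunum (0.076 and 2.41 RPKM) and ileum (0.061 and 1.65 RPKM). Trem2, a lipid receptor of macrophages, was higher by 6.68-fold, 2.03-fold and 2.62-fold. Lcn2 was higher by 8.66-fold, 2.23-fold and 2.49-fold, and Duox2 by 12.6-fold, 2.04-fold and 1.73-fold, while Reg3b, higher in jejunum, was lower in colon.

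The clock gene Per1 was at 0.669, 0.549 and 0.788 times its sham value in jejunum, ileum and colon, and Per2 at 0.791, 0.628 and 0.777 times, and the labels give no time of day. The clock list as a whole lay below the central range of random lists in ileum (median -0.24, 12 of 18 below 0) and inside it in jejunum (percentile 16.04) and colon (35.75). In the 3 tissues together camera called it down (adjusted p = 0.0188). The call was lost with a correlation estimated from 2 residual degrees of freedom (adjusted p = 0.622), a weak check. S100g, a calcium carrier gene, was higher in VSG by 10.8-fold in ileum and 3.86-fold in colon, and the calcium and vitamin D list lay above that range in ileum (percentile 99.99, median 0.35, 5 of 6 above 0) and inside it in jejunum (96.5) and colon (90.12). In VSG stomach the retinol carrier gene Rbp4 was at 443 RPKM against 6.52 RPKM in sham and the desaturase gene Scd1 at 515 against 7.74 RPKM, in the library that held liver RNA. Retnlb, an epithelial defence gene of type 2 immunity, was at 0.29 RPKM in sham and 3.02 RPKM in VSG ileum.

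Chance could be set against the fits by splitting the libraries in other ways. For genes over 5 tissues and in the small intestine the real number was 0, which every split reaches (100 of 100 drawn and 10 of 10), so these counts test nothing. For the lists, 20 of 100 splits gave as many as the real 28 and the highest other gave 32, so chance is not excluded for the number of lists. For genes in jejunum, ileum and colon 1 of 10 did, the real one, with 2 genes in the real split and 1 in the highest other, and 10 splits are too few for a share under 0.05. The highest numbers of genes, 8577 over 5 tissues and 10137 in the small intestine, came from splits that part the duodenum pair alone, a structure of the samples that sets VSG duodenum against the library labelled sham duodenum.

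With sham and VSG exchanged within tissues, which keeps the tissues in balance, 7 of 16 exchanges over 5 tissues gave at least 28 lists (highest other 31). In jejunum and ileum there are 2 such arrangements, of which the real one gave 107 genes and the other 1, and both gave 21 lists. In jejunum, ileum and colon there are 4, and the real one gave 2 genes and 21 lists against at most 0 genes and 19 lists in the others. With 2 and 4 arrangements a share under 0.05 is impossible, so these counts do not test chance. They show only how far the changes of the tissues agree.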
